A study of Mus musculus with 15 samples.

How the data were processed

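RNA was measured in cryopreserved primary hepatocytes of CD-1 mice, plated at 200000 cells per well on collagen. The cells were left to attach for 6 h and were then kept for 24 h in medium with 25% serum. The serum came from conventionally raised mice or from germ-free mice, which carry no microbiota. Growth hormone at 8 ng per ml, or vehicle, was added for 2 h at the end. Total RNA (250 ng) went into stranded libraries after depletion of ribosomal RNA, with 12 PCR cycles, and was read on a HiSeq 2500 with 100 cycles per read and 2 reads per fragment.

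The deposited values are raw read counts per gene over exons, as whole numbers without scaling. The authors named STAR 2.4.0i as the aligner and mm10 as the genome build. The counting program, its annotation, its strand setting and any filter are not given in the sources used here. Reads over overlapping genes were counted for both: Gm20425, a model that overlaps Trf, held 100.4% of the counts of Trf. A count for a gene that overlaps another can therefore hold reads of its neighbour, and genes of close families (major urinary proteins, Cyp2c, Cyp3a, sulfotransferases, serum amyloids) share reads that an aligner cannot place with certainty.

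The labels list 15 samples in 5 groups. The table holds 2 columns with the same name and lacks a column for 1 germ-free sample, so the 2 columns could not be assigned and were used in no step. That left 13 libraries: 3 of male hepatocytes in conventional male serum, 3 of female hepatocytes in conventional male serum, 2 of female hepatocytes in conventional female serum, 2 of female hepatocytes in germ-free female serum, and 3 of the latter with growth hormone. The design fixed before the data were examined had assumed all 15 samples. Each sex is represented by cells of its own donor stock, so that donor sex and donor are the same variable. The labels do not say whether replicates are separate cultures, animals or serum pools, so p-values here measure the spread between samples that may be technical replicates.

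Library totals ran from 34097400 to 48742274 counts. Replicates of the same group were compared by a chi-square per degree of freedom over genes with at least 20 counts. It ran from 5.46 to 53.36, so no library was a copy of another in its group. Libraries of different groups were not compared in this way. Of 38087 gene rows, 36308 had an identifier in GENCODE release M21, which gave the coordinates (mm10). Ratios of pooled counts carry an exact 95% Clopper-Pearson interval, which covers counting error only. Against a group without counts, a ratio is given as a lower bound at 3 counts over the group.

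Counts were scaled by TMM and filtered with filterByExpr (edgeR 4.0.16, minimum count 10), which left 17405 genes. One model of the 5 groups without covariates was fitted to the 13 libraries with 8 residual degrees of freedom. The biological coefficient of variation was 9%. The 4 comparisons were tested with the quasi-likelihood F test of edgeR, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. CPM values use library sizes scaled by TMM, except those of Malat1 and of satellite-like gene models, which use unscaled library totals. Fold changes are on the log2 scale with their standard error.

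Before the data were examined, 35 gene lists were fixed for liver functions, nuclear receptor and hormone targets, inflammation, stress, zonation, sex bias and markers of other liver cell types. Of their 634 memberships, 611 matched by symbol, 7 by gene identifier and 16 did not match. The 33 lists with at least 4 genes tested were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists. An estimated correlation was run as a check. The fry test, which does not compare a list with other genes, was also run and is given for the acute phase list with the sera. Counts adjusted over the list alone are a different measure: single members past the threshold with Benjamini-Hochberg adjustment over the members of that list.

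The genes named per comparison were also fixed by a rule. It took up to 8 rises and 8 falls with the largest fold change among genes past the threshold, with a mean count of at least 50 and no overlap between the groups' libraries. Predicted gene models, Y-linked genes and Xist were passed over there. It added up to 3 called members for each of at most 8 lists that had at least 3 called members or passed the list test. It also named Socs2, Cish, Igf1, Bcl6, Cux2, Cyp2b9, Cyp4a12a, Cyp7b1, Elovl3 and Cyp1a1 whatever their values, and the Y-linked genes and Xist between the sexes of the hepatocytes. Cux2 had too few counts to be tested. Single members named beside a small count outside this rule were picked after their values were seen.

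The method was tested on simulated data with the same depth and spread. Of genes given a true log2 change of 1, between 59.7% and 70.1% were recovered in the 4 comparisons, and of those given a change of 2, between 86.4% and 92.4%. False calls made up 2.7% to 5.7% of all calls. Genes were drawn independently with the spread estimated here, so these rates do not cover genes that vary together or a spread estimated wrongly. The relation between 2 comparisons that share a group was set against 100 simulations in which no gene differed, and against 9 for each fit with libraries left out or with the block. Each gene was drawn independently there too. Deviations that many genes of a library share are therefore missing from the simulated values and from their SD.

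The alternatives were DESeq2 size factors, library size only, no low-count filter, a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, a fit of only the 2 groups compared, the replicate number as a covariate, and leaving out each library in turn. In groups of 2 this leaves a lone sample, which is assumed to vary like the other groups. Leaving out both libraries with the most Xist reads was added after the data were seen. R 4.3.3 was used throughout.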

Results

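Gene expression was measured by RNA sequencing in 13 libraries of cultured mouse hepatocytes that differed in the sex of the donor, in the serum added to the medium and in a short exposure to growth hormone. Male hepatocytes in conventional male serum held 34097400, 37920635 and 36822989 counts per library, and female hepatocytes in the same serum 37370442, 34886134 and 39381453. Female hepatocytes in conventional female serum (replicates 2 and 3) held 47798248 and 42903075 counts, and those in germ-free female serum (replicates 2 and 3) held 40393393 and 35442492. With growth hormone on top of germ-free serum, the 3 libraries held 47725150, 41584999 and 48742274 counts. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and Xist, the RNA that silences an X chromosome, separated the male from the female cells as labelled. Kdm5d had 4132 counts over the 3 male libraries and 0 over the 3 female libraries in the same serum, a level at least 1500-fold higher at a floor of 3 counts over the group. Xist had 6 and 37639 counts in these groups, a ratio of 5760 towards the female cells (95% interval 2650 to 15700).

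The first principal component held 43.3% of the variance and set male apart from female hepatocytes. The second held 11.1%. Xist was most abundant in replicate 2 of conventional female serum (23315 counts) and in replicate 1 of the growth hormone group (32396 counts). Malat1, a nuclear noncoding RNA, stood at 11117 and 14581 CPM there and at 7375 to 11500 CPM in the other libraries. The deviations of the pair from their group means went together across genes (r = 0.25; genes are not independent replicates). In a group of 2 libraries the deviations mirror each other, so conventional female replicate 3 had r = -0.25 with the same hormone library. Which of the 2 departed cannot be told from this. Satellite-like gene models, which stand for repeats, made up 9.9 and 236.6 CPM in conventional female serum and 590.9 to 2416.7 CPM in all other libraries.

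**Figure D1:**
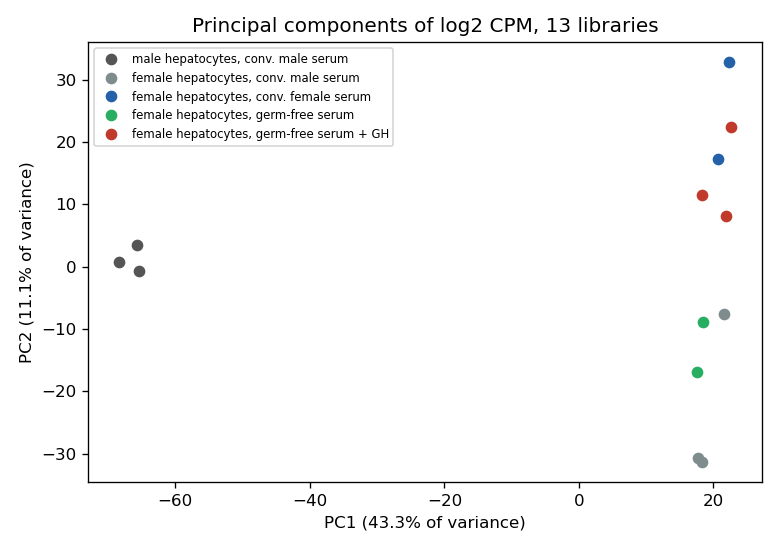
Scores of the 13 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis; each point is a library, coloured by group. Male hepatocytes lie apart on the first component, which holds 43.3% of the variance.

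The first comparison asked how female hepatocytes in serum of germ-free female mice (n = 2) differed from those in serum of conventionally raised female mice (n = 2). Acute phase genes fell as a group. The list holds plasma proteins that the liver secretes in inflammation, and also other genes such as Cebpd and Steap4. Of 26 tested members 14 fell (20 adjusted over the list alone) and the other 12 did not pass the test. Fga, the fibrinogen alpha chain (mm10 chromosome 3, 83026076 to 83033627), averaged 534 ± 3.15 CPM (SD, n = 2) in germ-free and 1450 ± 61.4 CPM (n = 2) in conventional serum, a log2 change of -1.44 ± 0.223 (SE). Saa4, a constitutive serum amyloid, fell by 1.12 and Crp, C-reactive protein, fell by 1.12 on the log2 scale. The list had a median of -0.58 and an adjusted p of 1.28e-18 with the preset correlation, and an adjusted p = 0.205 with an estimated correlation.

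Targets of PPAR-alpha, the receptor that drives fatty acid oxidation, fell in 11 of 30 members (18 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation). Ehhadh, an enzyme of peroxisomal beta-oxidation (chromosome 16, 21761287 to 21787807), changed by -1.87 ± 0.274, from 100 ± 57.1 to 27.3 ± 0.372 CPM, the largest fall among the named genes with all libraries but not without conventional replicate 2 (-1.13). Acot2 and Acot1, acyl-CoA thioesterases, changed by -1.36 and -0.82. Targets of the drug-sensing receptors CAR and PXR fell in 6 of 24 members (6 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation). Among them, Cyp2b10, the classic CAR target (chromosome 7, 25897620 to 25926624), went from 19.2 ± 0.972 to 6.89 ± 0.228 CPM (-1.48 ± 0.132, adjusted p = 4.72e-05), and Ugt2b34, a glucuronosyltransferase, changed by -0.68. Interferon-stimulated genes held 1 rise, Oasl1 (0.68), and 9 falls among 31 members, such as the GTPases Iigp1 (-1.05) and Igtp (-0.5), with 1 rise and 15 falls adjusted over the list alone and an adjusted p = 0.328 with an estimated correlation.

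Genes of hepatocyte identity showed 1 rise and 8 falls among 24 members (1 and 10 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation). They included Cps1 (-0.58), the entry enzyme of the urea cycle, and Apoa1 (-0.97), the main protein of HDL. In the circadian clock list 4 of 21 members fell (8 adjusted over the list alone), led by Per2 (-1.17), at an adjusted p = 0.232 with an estimated correlation. The same p with an estimated correlation, 0.232, held for the bile acid list, with 1 rise and 3 falls among 19 members (1 and 5 adjusted over the list alone), and for the LXR cholesterol efflux list, with 3 falls among 8 (6 adjusted over the list alone). The rise was that of Abcb11 (0.54), the bile salt export pump; Abcb4, the phospholipid exporter of bile, changed by -1.02 and Baat, which conjugates bile acids, by -1.28. Abcg5 and Abcg8, the sterol exporters, changed by -0.77 and -0.78.

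The largest rises were those of Dok7 (3.14 ± 0.543), an adaptor protein best known from muscle, Mex3a (2.71), an RNA-binding protein, and Irx5 (2.59) and Irx3 (2.25), neighbouring homeobox genes. Dok7 changed by 2.43 without conventional replicate 2, below Mex3a, and by 4.45 without conventional replicate 3. Cxcl10, an interferon-inducible chemokine, rose from 3.54 ± 0.104 to 18.9 ± 0.898 CPM (2.41 ± 0.276); it overlaps Art3 in the annotation. Npy, neuropeptide Y, rose by 2.28, Slc30a3, a zinc transporter, by 2.27 and Tdo2, a tryptophan-degrading enzyme of the liver, by 2.15. Without conventional replicate 3, Irx5 rose by 3.39 and Tdo2 by 3.02. After Ehhadh, the largest falls were those of Ppp1r3c (-1.81), a glycogen-targeting phosphatase subunit, Fgf21 (-1.67), a fasting hormone, Hpgd (-1.66), which breaks down prostaglandins, and Necab1 (-1.66). Next came Hamp (-1.61), the iron hormone hepcidin, Slc25a47 (-1.61), a mitochondrial carrier, and Synm (-1.55). Among mediators of growth hormone signalling, Socs2 changed by -0.5 (adjusted p = 0.0291), Cish by 0.61 (0.0281) and Bcl6 by 0.56 (0.0173). Igf1 (-0.19), Cyp2b9 (-0.29), Cyp7b1 (-0.51), Elovl3 (-0.19) and Cyp1a1 (-0.34) did not pass, and Cyp4a12a had 1 and 0 counts. Igf1 gained a call without conventional replicate 3 (-0.33, adjusted p = 0.0366).

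In all, 498 genes rose and 617 fell, 1115 of 17405. Of 33 lists, 12 fell and 2 rose, cell cycle (median 0.23) and stellate cells and fibroblasts (median 0.4, no single member past the threshold), at an adjusted p = 0.433 each with an estimated correlation. With an estimated correlation, camera called 0 of the 33 lists (5 at an unadjusted p under 0.05). Both rises also lost their calls at the preset correlation, without conventional replicate 2 and without germ-free replicate 3. Of the falls, genes of the periportal zone of the liver lobule lost theirs without conventional replicate 3 or either germ-free replicate. Pericentral genes lost theirs without conventional replicate 2 or germ-free replicate 2. For genes known to be higher in female liver this held without conventional replicate 3 or germ-free replicate 2. The count of genes was 274 without conventional replicate 2, 343 without germ-free replicate 2, 325 without germ-free replicate 3, 611 in a fit of only these groups, 1731 without the low-count filter and 367 without both libraries rich in Xist. In the first 3 of these fits 6, 5 and 7 acute phase members fell, 4, 6 and 5 PPAR-alpha targets and 0, 1 and 5 interferon-stimulated genes. Calls of Tdo2, Fgf21, Hamp, Necab1, Synm, Baat, Abcg5, Abcg8 and Socs2 were lost in each (for Socs2 at 0.4, 0.107 and 0.186). Cish lost its call without any 1 of the 4 libraries (adjusted p 0.0753 to 0.167), Bcl6 without all but germ-free replicate 3 (0.0539 to 0.18). The same held for Iigp1 without conventional replicate 2 (0.0503), Igtp also without germ-free replicate 2 (0.0632 and 0.0598), and Apoa1 without germ-free replicate 2 (0.0609).

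The second comparison asked how serum of conventionally raised male mice (n = 3) differed from that of conventionally raised females (n = 2) in its effect on female hepatocytes. Acute phase genes again fell as a group, with 17 of 26 members past the test (20 adjusted over the list alone) and a median of -0.69. Fga averaged 349 ± 68.7 CPM (SD, n = 3) in male and 1450 ± 61.4 CPM (n = 2) in female serum (-2.05 ± 0.199). Hp, haptoglobin, which binds free haemoglobin, fell from 2350 ± 437 to 704 ± 71.2 CPM (-1.74 ± 0.193), and Crp changed by -1.79 and Saa4 by -1.01. The list reached an adjusted p of 1.89e-30 with the preset correlation and an adjusted p = 0.0554 with an estimated correlation.

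NF-kB targets and chemokines, which carry inflammatory signals, showed 1 rise, Cxcl10 (1.13), and 9 falls among 25 members (1 and 11 adjusted over the list alone; adjusted p = 0.0554 with an estimated correlation). Cxcl2 and Cxcl1, which attract neutrophils, fell to 9.59 ± 1.79 from 27.2 ± 2.19 CPM (-1.5 ± 0.115) and to 64 ± 6.54 from 138 ± 3.84 CPM (-1.1 ± 0.086). Cd14, a receptor for bacterial lipopolysaccharide, changed by -0.44. Of 31 interferon-stimulated genes 12 fell, with 1 rise and 15 falls adjusted over the list alone (adjusted p = 0.387 with an estimated correlation), among them Iigp1 (-1.26), Ifi44 (-0.67) and Ifit1 (-0.63). CAR and PXR targets fell in 6 of 24 members (6 adjusted over the list alone; adjusted p = 0.164 with an estimated correlation), with Cyp2b10 at -1.59 ± 0.117, Ugt2b34 at -0.91 and Cyp3a13 at -0.4.

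Genes of the periportal zone of the liver lobule fell in 4 of 13 members (5 adjusted over the list alone; adjusted p = 0.137 with an estimated correlation), with Hsd17b13, a lipid droplet enzyme, at -1.42, Cdh1, E-cadherin, at -0.57 and Cps1 at -0.54. In the bile acid list, Abcb4 (-1.01) and Baat (-1.03) fell and Cyp8b1, which makes cholic acid, rose by 0.55, out of 19 members (1 rise and 5 falls adjusted over the list alone; adjusted p = 0.266 with an estimated correlation). Of 33 genes known to be higher in female liver, 3 fell (3 adjusted over the list alone): Cyp2a4 (-1.01), a steroid hydroxylase, Vldlr (-0.54), a lipoprotein receptor, and Nipal1 (-0.53), at an adjusted p = 0.143 with an estimated correlation. Of 27 genes known to be higher in male liver, 2 rose, Nox4 (1.32) and Bcl6, and 1 fell, Gstp1 (-0.24), with 4 and 2 adjusted over the list alone and an adjusted p of 0.663 with the preset correlation. Of 21 clock genes 3 fell, Per2 (-1) and Tef (-0.47) among them (5 adjusted over the list alone; adjusted p = 0.266 with an estimated correlation).

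The largest rises belonged to Trbc1 (2.86 ± 0.339), a constant segment of the T cell receptor, Mex3a (2.58), F13a1 (2.43), a coagulation factor subunit made by macrophages, Arc (2.1), an immediate early gene, and Slc30a3 (1.98). They were followed by Irx5 (1.91), Htr2b (1.9), a serotonin receptor gene that overlaps Psmd1, and Tmprss11f (1.85), a membrane protease. Without female serum replicate 2, F13a1 rose by 3.45 and Arc by 3.21; without female serum replicate 3, Arc rose by 1.49 and Irx5 by 2.71. Besides acute phase genes, the largest falls were those of Ppp1r3c (-2.11), Hamp (-2.01), Id1 (-1.85), a target of BMP signalling, Fam43a (-1.8) and Acnat2 (-1.73). Socs2 changed by -0.39 (adjusted p = 0.0451), Cish by 0.72 (0.00554) and Bcl6 by 0.43 (0.0374). Igf1 (0.23), Cyp2b9 (-0.35), Cyp7b1 (-0.63), Elovl3 (0.26) and Cyp1a1 (-0.93) did not pass, and Cyp4a12a had 4 and 0 counts. Igf1 gained a call without female serum replicate 2 (0.37, adjusted p = 0.0251), and Cyp7b1 with library size only (0.0475), without the low-count filter (0.00916) and with DESeq2 (0.0328).

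Altogether 687 genes rose and 845 fell, 1532 of 17405. Of 33 lists, 11 fell and 2 rose, cell cycle (median 0.21, adjusted p = 0.59 with an estimated correlation) and cholesterol synthesis (median 0.11, adjusted p = 0.742 with an estimated correlation). In all, camera called 0 with an estimated correlation (6 at an unadjusted p under 0.05). Both rises also lost their calls at the preset correlation, without male serum replicate 2 (adjusted p = 0.106 and 0.119), male serum replicate 3 (0.127 and 0.344) and female serum replicate 2 (0.36 and 0.33). Of the falls, the LXR and PPAR-alpha lists lost theirs without male serum replicate 1 (0.0617 and 0.188) and male serum replicate 3 (0.0575 and 0.0882). Without female serum replicate 2 both lost their calls too, and the PPAR-alpha list turned to the direction of a rise. The count of genes was 663 without female serum replicate 2, 905 without female serum replicate 3, 957 without male serum replicate 1, 468 in a fit of only these groups and 825 without both libraries rich in Xist. Without female serum replicate 2, falls numbered 11 among acute phase, 1 among interferon-stimulated and 4 among NF-kB members. Calls were lost there for Ifi44 (0.0611), Ifit1 (0.101), Irx5 (0.0654), Baat (0.0839) and Cdh1 (0.0835). Socs2 lost its call without each library except female serum replicate 3 (0.0664 to 0.536), and Bcl6 without each except male serum replicate 2 (0.0813 to 0.153). Cyp8b1 lost its call without each except male serum replicate 1 (0.0519 to 0.197) and Cish without female serum replicate 3 (0.0625).

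**Figure D2:**
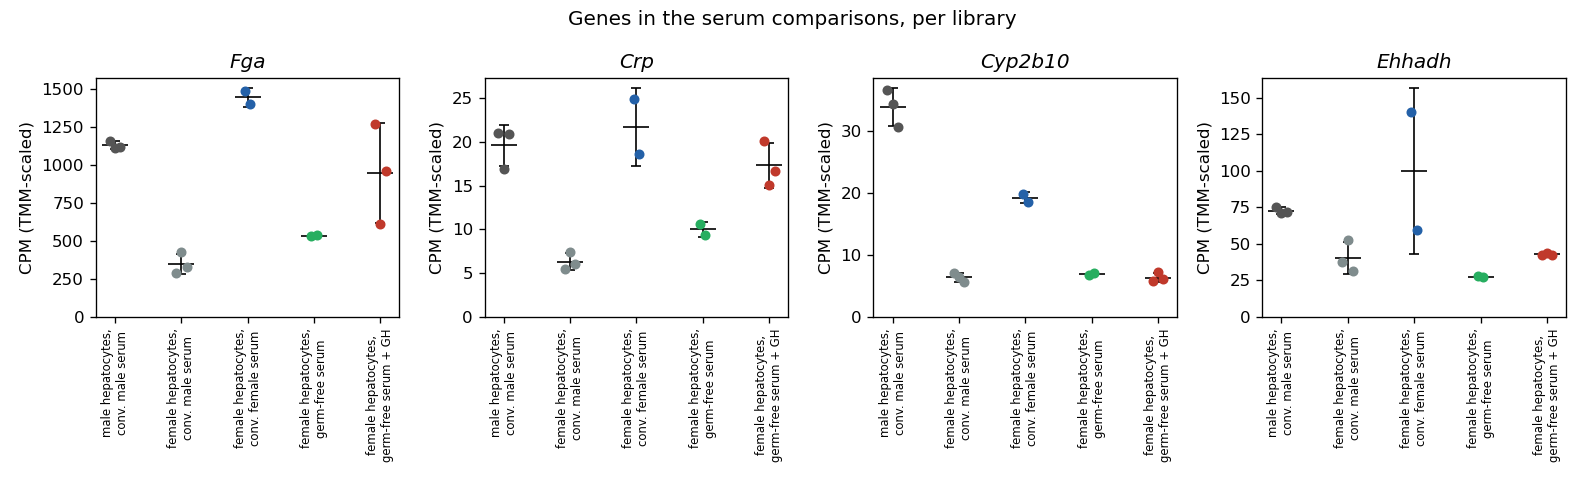
CPM (TMM-scaled) of Fga, Crp, Cyp2b10 and Ehhadh in each library of the 5 groups, on linear axes from 0; points are libraries, horizontal lines group means and bars the SD (n = 2 or 3). In female hepatocytes without hormone, each gene has its highest mean in conventional female serum, where Ehhadh spreads most (SD 57.1 CPM).

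The third comparison asked how male (n = 3) and female (n = 3) hepatocytes differed in the same conventional male serum. Major urinary proteins, pheromone carriers that male liver secretes, were far higher in male cells. Mup20, darcin (chromosome 4, 62050234 to 62054158), averaged 215 ± 13.1 CPM (SD, n = 3) in male and 0.242 ± 0.187 CPM (n = 3) in female cells, a ratio of pooled counts of 866 (95% interval 599 to 1300). Mup12 had 464 and 0 counts, at least 168-fold higher at a floor of 3 counts over the group. Cyp4a12a, a male-specific fatty acid hydroxylase, was 458 times higher (179 to 1680), and Hsd3b5, a male-specific steroid enzyme, 79.7 times (33.8 to 247). On the log2 scale, leaving out a female library moved Mup20 from 9.74 to 10.46 (replicate 3), Cyp4a12a from 8.72 to 9.96 (replicate 1) and Hsd3b5 from 6.22 to 7.78 (replicate 2). Mup21, Mup7, Mup19 and Mup18 rose by 7.4, 7.02, 6.32 and 6.05 on the log2 scale, and Mup3, the most abundant of those named, by 3.91 to 2180 ± 92.7 CPM.

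Of 27 genes known to be higher in male liver, 23 rose and 1, Bcl6, fell (24 and 1 adjusted over the list alone), with a median of 2.75, also with members at 0 in a group set to their bound; the adjusted p was 1.48e-05 with an estimated correlation. Of 33 genes known to be higher in female liver, 25 fell and 4 rose (25 and 4 adjusted over the list alone; median -2.07, also with bounds; adjusted p = 0.000322 with an estimated correlation). The 4 were Cyp17a1 (3.99), a steroid enzyme, Cd36 (0.94), a fatty acid transporter, Vldlr (0.61) and Sult1e1 (0.59), the oestrogen sulfotransferase. A1bg, a plasma protein of female mouse liver, had 3 counts in male and 1792 in female cells, a ratio of 549 towards the female cells (187 to 2660). The ratio was 329 (179 to 688) for Cyp2c69 and 326 (58.2 to 12900) for the sulfotransferase Sult3a1, which had 1 and 355 counts. Without male replicate 2, the log2 change of A1bg went from -8.96 to -12.34 and that of Sult3a1 from -7.95 to -10. Cyp2c40 (-4.55), Cyp2a4 (-4.39), Cyp3a44 (-4.03) and Cyp2b9 (-3.77), all cytochromes P450, fell, as did Tff1 (-4.29), a trefoil peptide, and Dlgap1 (-4.26), a scaffold protein of synapses. On the X chromosome 4 of 5 genes that escape or direct inactivation fell (4 adjusted over the list alone; adjusted p = 0.0084 with an estimated correlation), namely Xist, Kdm5c (-0.81), Eif2s3x (-0.75) and Kdm6a (-0.5).

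Acute phase genes were higher in male cells in 22 of 26 members (23 adjusted over the list alone; median 1.53; adjusted p = 0.0131 with an estimated correlation). Hpx, which binds haem, averaged 6510 ± 257 and 2200 ± 72.5 CPM (1.57 ± 0.065), and Orm2 and Saa2 rose by 2.38 and 1.5. Periportal genes rose in 11 of 13 members (11 adjusted over the list alone; adjusted p = 0.000188 with an estimated correlation), with Hsd17b13 at 3.48, Cdh1 at 2.78 and Cps1 at 2.38. Genes of hepatocyte identity rose in 16 of 24 members and fell in 3 (16 and 3 adjusted over the list alone; adjusted p = 0.0242 with an estimated correlation). Alb, albumin, averaged 17700 ± 534 and 6770 ± 193 CPM (1.39 ± 0.066), and Serpina1a, an antitrypsin, rose by 2.03. Foxa2 (-0.63) and Hnf4a (-0.33), transcription factors of the hepatocyte, were among the falls. CAR and PXR targets rose in 16 of 24 members and fell in 2 (17 and 3 adjusted over the list alone; adjusted p = 0.0131 with an estimated correlation), with Cyp2b10 at 2.41, Cyp3a11 at 1.87, Cyp2c37 at -3.25 and Por, the reductase that feeds electrons to cytochromes P450, at -0.78. Markers of liver sinusoidal endothelial cells also rose, in 9 of 15 members with 1 fall, Dpp4 (-0.4), and 10 and 1 adjusted over the list alone (median 0.72; adjusted p = 0.0084 with an estimated correlation).

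Between male and female cells, Socs2 (-0.48), Cish (-0.54) and Bcl6 (-0.76) fell, Cyp7b1 (1.34), Elovl3 (3.59) and Cyp1a1 (1.19) rose, and Igf1 (0.08) did not pass. Cyp1a1 lost its call without male replicate 2 (0.134) and without female replicate 1 (0.0595). In total 3065 genes rose and 3314 fell, 6379 of 17405. With library size only, the median over all genes lay at -0.108 and the split became 2349 rises and 4643 falls, so that changes are best read relative to this shift. Of 33 lists, 13 rose and 3 fell, and 10 kept a call with an estimated correlation (8 rises, 2 falls). Among the 6 that did not were the cell cycle list, with 1 rise, Ccne2 (0.65), and 13 falls among 24 members (2 and 14 adjusted over the list alone; adjusted p = 0.338 with an estimated correlation), and the bile acid list, with 10 rises and 2 falls, Abcb11 (-0.85) and Klb (-0.84), among 19 (13 and 2 adjusted over the list alone; adjusted p = 0.108 with an estimated correlation).

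The fourth comparison asked what 2 h of growth hormone (n = 3) changed in female hepatocytes kept in germ-free serum, against vehicle (n = 2). NF-kB targets and chemokines rose together: 20 of 25 members rose (22 adjusted over the list alone), with a median of 1.13 and an adjusted p of 1.02e-06 with an estimated correlation. Ccl20, which attracts lymphocytes and dendritic cells (chromosome 1, 83116766 to 83119167), averaged 9.24 ± 1.77 CPM (SD, n = 3) with hormone and 0.244 ± 0.0293 CPM (n = 2) without, a ratio of pooled counts of 38 (95% interval 24.2 to 63.3). Il1b, an interleukin that drives inflammation (chromosome 2, 129364570 to 129371139), had 1205 and 3 counts, a ratio of 225 (76.7 to 1090), and Il6, which induces the acute phase response, had 376 and 2, a ratio of 105 (28.9 to 872). The ratio was 122 (59.2 to 305) for Il1a, 86.5 (33.6 to 318) for Nos2, the inducible nitric oxide synthase, 45.1 (22.7 to 105) for Ccl4 and 20.1 (12.6 to 34.1) for Ccl3. Log2 changes of Il6, Nos2 and Ccl3 were 6.58, 6.34 and 4.29, against 9.79, 5.28 and 3.57 without vehicle replicate 2 and 5.75, 10.51 and 5.56 without vehicle replicate 3. That of Il1b went from 7.71 to 8.33 without vehicle replicate 3. Vcam1, an adhesion molecule for leukocytes, rose from 6.32 ± 0.306 to 46 ± 3.29 CPM (2.86 ± 0.174).

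Acute phase genes rose in 6 of 26 members (17 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), led by Il1rn (2.37), the antagonist of the interleukin receptor, Cebpd (1.87), a transcription factor, and Steap4 (1.51), a metalloreductase. In the list of growth hormone and STAT5 targets, 2 of 19 members rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). Socs2, a feedback inhibitor that growth hormone induces, rose from 15 ± 0.619 to 28.5 ± 2.47 CPM (0.92 ± 0.119, adjusted p = 0.000494), Socs3, a related inhibitor, rose by 0.69. Bcl6, a repressor that growth hormone lowers, fell from 48.5 ± 6.61 to 29.5 ± 3.84 CPM (-0.72 ± 0.118, adjusted p = 0.00606). Angptl4 (0.8), which inhibits lipoprotein lipase, was the single called member of 30 PPAR-alpha targets (9 adjusted over the list alone; adjusted p = 0.473 with an estimated correlation). The other large falls were those of Slc30a3 (-1.07), Dusp4 (-1.01), a MAP kinase phosphatase, Rnf39 (-0.94), Ccl6 (-0.79), Trim15 (-0.78), Mex3d (-0.75) and Lmcd1 (-0.51). Cish (0.42, adjusted p = 0.235), Igf1 (0.22), Cyp2b9 (-0.05), Cyp7b1 (0.42), Elovl3 (0.24) and Cyp1a1 (-0.48) did not pass, and Cyp4a12a had counts at or under the floor. Cish gained a call in a fit of only these groups (0.42, adjusted p = 0.0178) and without the low-count filter (0.43, 0.000302).

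Growth hormone raised 89 genes and lowered 13, 102 of 17405. Of 33 lists, 9 rose and 2 fell, and with an estimated correlation the NF-kB list alone kept its call. Without vehicle replicate 2 the lists numbered 5, growth hormone and STAT5 targets no longer among them (adjusted p = 0.123), and without hormone replicate 1 they numbered 7. Markers of stellate cells and fibroblasts had a median of -0.41 (adjusted p = 0.473 with an estimated correlation). The count of genes was 33 and 38 without vehicle replicates 2 and 3, 55, 190 and 57 without hormone replicates 1, 2 and 3, 796 without the low-count filter, 272 with DESeq2, and 156 in a fit of only these groups. In the fits without 1 library, 16 to 19 NF-kB members and 2 to 13 acute phase members rose. Without vehicle replicate 2, Bcl6 (0.216), Socs3 (0.168) and Steap4 (0.102) lost their calls, the last also without vehicle replicate 3 (0.0938). The rise of Angptl4 and the 7 falls named besides Bcl6 lost their calls in 4 or 5 of these 5 fits.

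**Figure D3:**
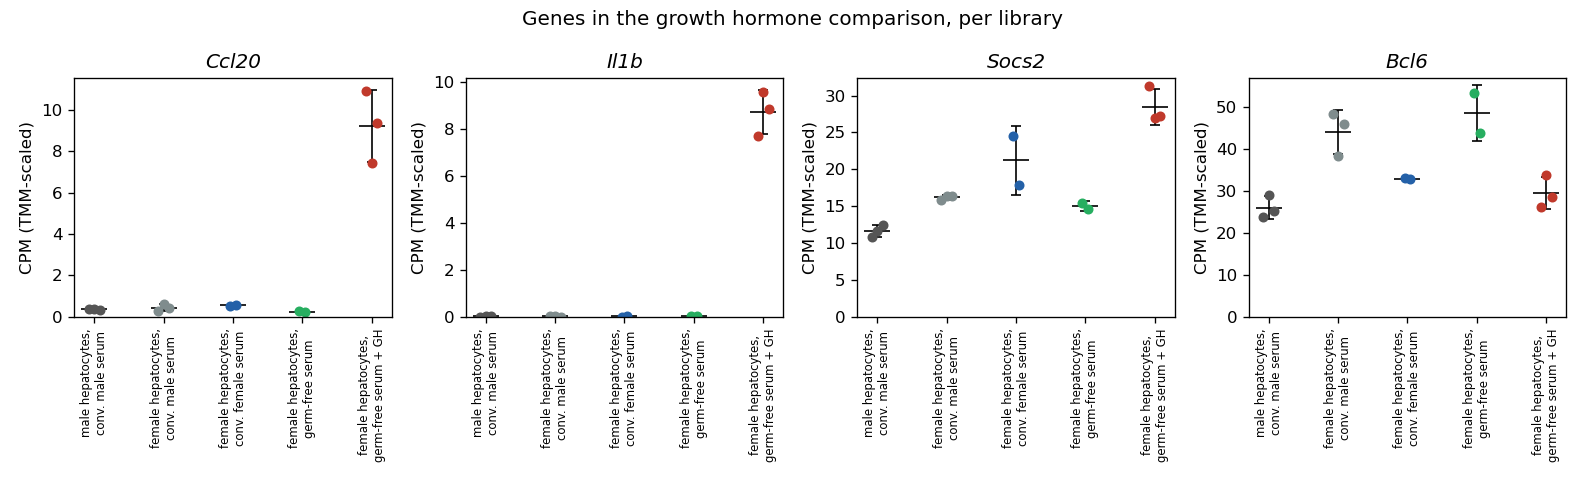
CPM (TMM-scaled) of Ccl20, Il1b, Socs2 and Bcl6 in each library of the 5 groups, on linear axes from 0; points are libraries, horizontal lines group means and bars the SD (n = 2 or 3). Ccl20 averages 9.24 CPM with growth hormone and 0.244 CPM in the same serum without it.

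**Figure D4:**
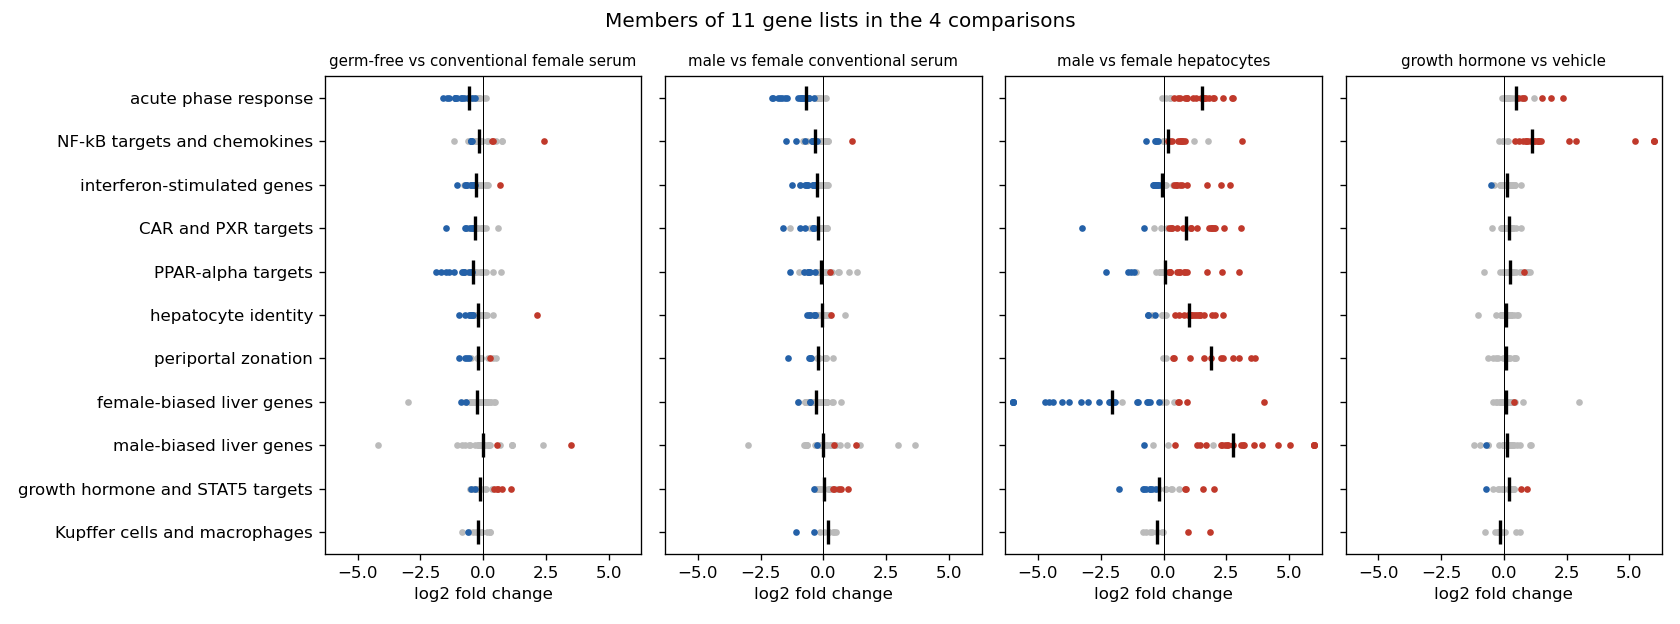
Log2 fold change of each tested member of 11 gene lists in the 4 comparisons; red points passed the test upwards, blue points downwards and grey points did not pass, black bars are medians, and values beyond 6 in either direction are drawn at 6. The acute phase median lies at -0.58, -0.69, 1.53 and 0.5 from left to right.

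Whether the effects of germ-free and of male serum went together was asked across all 17405 genes, which are not independent replicates. Both comparisons share the conventional female libraries, which makes unchanged genes correlate, and the 2 libraries cannot be split between them. Log2 changes correlated at r = 0.674 (Spearman rho 0.65), against 0.523 ± 0.012 (SD of 100 simulations without change; rho 0.477), and their covariance was 0.163 against 0.056, a difference of 0.107. The simulations drew each gene independently. A deviation that many genes share in the conventional female libraries could thus give part or all of this difference. With both sera 391 genes were called lower than with conventional female serum, Fga, Crp, Cyp2b10 and Ppp1r3c among them. Higher calls with both numbered 308, including Mex3a, Irx5 and Slc30a3. Independent calls would give 30 and 19.7 such genes, a value that leaves out the shared libraries, and the simulations 0.04 and 0.03, which leave out the effects. Part of the excess over either may come from the shared libraries. With 1 library left out, the simulated r changed as well: r was 0.502 against 0.367 in simulation without germ-free replicate 2, 0.814 against 0.73 without conventional female replicate 3, and 0.758 against 0.747 ± 0.01 (SD of 9) without conventional female replicate 2. The covariance differed from its simulated value by 0.101 to 0.123 over these fits, except 0.262 without conventional female replicate 3.

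Whether growth hormone moved genes back towards their level in conventional serum was asked in the same way, with the germ-free libraries as the shared group. Here r was -0.549, against -0.576 ± 0.01 in simulation, and rho -0.595 against -0.507, while the covariance was -0.109 against -0.062, a difference of -0.047. Pearson r thus lay no further from 0 than in simulation, while rho and the covariance lay further from it. Genes were drawn independently here as well, so a deviation that many genes share in the germ-free libraries could give this. Of genes that fell with germ-free serum, 33 rose with growth hormone, among them Crp, Saa4, Steap4, Cxcl1, Cxcl2 and Socs2, and 10 that rose with germ-free serum fell with the hormone, Slc30a3 and Bcl6 among them. Independent calls would give 3.2 and 0.4, and the simulations gave 0.03 and 0; the shared libraries favour opposite calls, so part of the excess may come from them. In the same direction, 2 genes rose in both (2.5 with independent calls), Csf2, a growth factor of myeloid cells, and Ier3, an early response gene, and 0 fell in both (0.5). With 1 library left out, r was -0.763 against -0.801 in simulation without germ-free replicate 2, -0.674 against -0.772 without germ-free replicate 3, -0.408 against -0.433 without conventional female replicate 2 and -0.484 against -0.527 without hormone replicate 1. It lay further from 0 than in simulation without conventional female replicate 3 (-0.471 against -0.436) and hormone replicate 2 (-0.549 against -0.522). Without hormone replicate 3 it lay within the simulated spread (-0.525 against -0.52 ± 0.012, SD of 9). The covariance differed from its simulated value by -0.114 without germ-free replicate 2, -0.016 without germ-free replicate 3 and -0.077 without conventional female replicate 3, and by -0.057 to -0.032 in the other fits.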

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

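The fit without both libraries richest in Xist was chosen only after the results were seen; the others were planned. Of the values for named genes, 1940 kept direction and side of the threshold over these fits, 160 lost and 8 gained a call, and 8 changed sign, none of them called: Igf1 between the hepatocytes came to 0 with library size only, and Elovl3 with male serum to -0.14 without both rich libraries. Without 1 library, Elovl3 ran from -0.14 to 0.76 with male serum, -0.59 to 0.31 with germ-free serum and -0.04 to 0.37 with growth hormone, and Cyp4a12a, with counts near 0, from 0 to 3.14 with germ-free serum and -0.16 (-0.13 without vehicle replicate 3) to 3 with growth hormone. The cause was not tested. Without 1 library, counts of genes ran from 274 to 1225 for germ-free serum, 663 to 1652 for male serum, 5248 to 6090 for male hepatocytes and 33 to 190 for growth hormone, fewer samples being part of the cause; counts of lists ran from 11 to 14, 9 to 14, 16 in each fit and 5 to 12. The correlation of germ-free with male serum ran from 0.502 to 0.814, that with growth hormone from -0.763 to -0.408; simulated values without change moved too, from 0.367 to 0.747 and -0.801 to -0.433. An estimated correlation between genes left 0, 0, 10 and 1 lists in the 4 comparisons. No low-count filter gave 1731 genes for germ-free serum and 796 for growth hormone, DESeq2 272 for growth hormone, and a fit of only the groups compared 611, 468 and 156 for germ-free serum, male serum and growth hormone. Genes with a mean of at least 1 CPM gave correlations of 0.772 and -0.525 (0.534 and -0.562 in simulation). The fit without both rich libraries gave 367 and 825 genes for the sera and correlations of 0.757 and -0.39 (0.737 and -0.403 in simulation). For these the cause was not tested. The replicate number as a block gave 62 genes for growth hormone and -0.528 for the second correlation (-0.562 in simulation). Deviations of 23 pairs of libraries with the same number correlated at -0.17 to 0.13 (median -0.01). For 7 of 13 libraries the best match in another group bore the same number. Whether the numbers mark a pairing therefore stays open, and the cause of the fewer calls was not tested. With library size only the counts for each comparison stayed within 1.5 times, as they did with DESeq2 size factors and the stricter filter. No difference between the sera or with growth hormone was detectable at this depth for Cyp4a12a, with 0 to 4 counts over each group of female cells, or Elovl3, with 8 to 17.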

Other observations

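Gene families, which were grouped by symbol after the results were seen, gave further detail. Between male and female hepatocytes, all 15 major urinary protein genes tested rose (median log2 change 4.38), 25 of 28 serpin A genes, which code for protease inhibitors of plasma, rose (median 1.58; 24 with library size only), and 13 of 14 complement genes, the plasma part of innate defence, rose (median 1.11). Ugt2b glucuronosyltransferases rose in 5 of 7 members (median 2.1). Sulfotransferases went both ways, with 5 rises and 8 falls among 14. Cytosolic ribosomal proteins had a median of 0 over 78 genes, with 8 rises and 4 falls, and of -0.09, with 3 rises and 15 falls, with library size only. The Iroquois homeobox genes fell in male cells, all 4 of those tested (median -1.74).

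In female hepatocytes, Irx3 and Irx5, the Iroquois genes with the most counts, rose with germ-free serum (2.25 and 2.59) and with male serum (1.59 and 1.91), under each of the 3 scalings. Of 27 genes with symbols that start with Apo, 7 fell with germ-free serum and 5 with male serum. Apoa4 (-0.66) and Apoa1 (-0.97), apolipoproteins that carry lipids in plasma, were among the 7. Not every gene with such a symbol codes for an apolipoprotein. Ugt2b genes fell in 3 and 4 of 7. The metallothioneins Mt1 and Mt2, which bind zinc and copper, fell with male serum (-0.5 and -0.6). Of 26 chemokine ligand genes, 10 rose and 1 fell with growth hormone. Set directly against each other, germ-free female and conventional male serum differed in 78 genes (32 higher and 46 lower with germ-free serum; 1822 at an unadjusted p under 0.05), and the acute phase list had a median of 0.1 with 1 member higher.

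For the patterns weighed here, the tests that leave out single libraries were planned; those on cell types, scaling, chromosomes, genes that fell in both sera, other divisions of the samples and the direct contrast of sera were chosen only after the results were seen.

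NF-kB targets and chemokines rose with growth hormone. A single library does not account for it, since at least 16 members rose with any 1 of the 5 libraries left out. More macrophages in the hormone wells are argued against by the Kupffer cell and macrophage list, with a median of -0.17 and with Cd68, its most abundant member, at 95.8 CPM with and 124 CPM without hormone, although a change within macrophages already present stays open. An inflammatory stimulus such as endotoxin carried with the hormone preparation may equally give 20 called members, and it cannot be told apart from the hormone because both entered the same wells. The biological reading, that the hormone itself raised these genes, is also open, as no other preparation was tested.

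Acute phase and hepatocyte identity genes were higher in male hepatocytes. Fewer other cells of every type in the male culture are argued against by endothelial markers, of which 9 of 15 were called higher in male cells and 1 lower (median 0.72, SE 0.25), with Pecam1 at 10.4 and 2.74 CPM and Stab2 at 9.67 and 3.74 CPM. Stellate cell and fibroblast markers had 7 of 15 called higher and 1 lower (median 0.55, SE 0.26). The SEs of these medians treat the members of a list as independent. Kupffer cell and macrophage markers had a median of -0.27 (SE 0.33), with 2 of 10 called higher and 0 lower, which does not settle the share of these cells. The choice of TMM over library size does not account for the rises, since 38 members of both lists still rose with library size only. That choice moved the median over all genes only from -0.021 to -0.108, so a larger error of scaling was not tested. Whether donor stock or donor sex is the source cannot be told apart with cells of 1 source per sex; 6109 of the 6379 called genes lie outside the sex chromosomes, which either may give.

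The acute phase list was lower with germ-free and with male serum than with conventional female serum at the preset correlation between genes, but not past the threshold with an estimated correlation (adjusted p = 0.205 and 0.0554). By fry, which does not compare the list with other genes, the adjusted p was 0.0125 and 0.00242. Either conventional female library alone is argued against as the cause by a median that stayed at -0.41 or below when 1 of them was left out. A smaller share of hepatocytes would raise the markers of all other cell types alike and lower hepatocyte genes alike. With germ-free serum the markers do not decide. Medians were 0.4 for stellate cell and fibroblast markers and -0.19 for Kupffer cell and macrophage markers, a difference of 0.59 (SDs of members 0.43 and 0.39). These lists were picked as the highest and the lowest after their values were seen, which favours a gap. In the stellate list 0 of 15 members were called, and in the Kupffer list 1 of 10, which was lower. A change in stellate cells stays open there. Hepatocyte identity genes had a median of -0.22, in the direction of a smaller share. It lay only 0.36 above that of the acute phase list (SE 0.19), so a smaller share of hepatocytes stays open with germ-free serum. With male serum the median of hepatocyte identity genes was -0.05, which lay 0.64 above that of the acute phase list (SE 0.18). Both SEs were taken over genes as if independent, not over libraries. Members correlated at an estimated 0.25 in the identity list and 0.37 in the acute phase list, so these SEs are too small. The gap therefore does not decide, and a smaller share of hepatocytes stays open with male serum too. Of the 24 identity genes 6 fell and 1 rose, in the direction of a smaller share. The list was called lower by camera without male serum replicate 2 (adjusted p = 0.00868, against 0.0765 with all libraries). Medians of stellate, endothelial, cholangiocyte and Kupffer cell markers were 0.02, 0.04, 0 and 0.19 there. A difference in handling of the conventional female wells, whose satellite-like RNA was also low, may give the 391 genes that fell in both comparisons and cannot be told apart from the serum, since both are the same libraries. A biological effect of conventional female serum stays open beside it, untested.

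The 6 libraries of male and female hepatocytes in male serum can be divided into 10 splits of 3 and 3. The real split gave 6379 genes and the highest other split 0 by edgeR (480 to 997 genes at an unadjusted p under 0.05 over the others), 1 of 10 as large. For lists the real split gave 16 and the highest other 13, again 1 of 10. A share under 0.05 cannot be reached with 10 splits. Every other split also mixed male and female libraries in both groups, which turns the difference between the cells into spread within groups. The counts of the other splits are therefore no measure of chance. Mir5105 took 2.09% of the counts in replicate 1 of female hepatocytes in male serum and 0.48% to 1.25% in the other libraries.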
